A study of Mus musculus with 8 samples.

How the data were processed

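Mouse J1 embryonic stem cells (strain 129S4/SvJae) were profiled by ribosome profiling, which sequences the mRNA fragments that ribosomes protect from nuclease (ribosome-protected fragments, RPF, or footprints), and by sequencing of total RNA. Per the labels' protocols, the cells were grown without feeders on gelatin in medium with serum and leukemia inhibitory factor. Infection took place on day 0, for which the protocol names 2 control shRNAs (shNT and shGFP) and 2 shRNAs against eIF4A2, and the cells were selected with 1 μg/mL puromycin for 3 days and taken on day 4.5. Cycloheximide at 0.1 mg/mL was given for 1 min before lysis to hold ribosomes on mRNA. Libraries came from the TruSeq Ribo Profile kit with Ribo-Zero Gold depletion of rRNA and were read as single-end 50 bp reads on a HiSeq2500, and each RPF library was sequenced 4 times. The 8 libraries fall into 4 groups of 2, namely RPF of the eIF4A2 knockdown, RPF of the control, total RNA of the knockdown and total RNA of the control. The protocol calls the samples of a group biological replicates. Which of the named shRNAs each replicate received is not given in the sources used here.

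The authors deposited 1 table of footprints (12818 genes) and 1 table of total RNA (13436 genes), both already cleared of genes with few reads. The library columns hold what is called signal here, which the authors made by dividing the reads of each gene by an effective library size. They are on the CPM scale (reads scaled to a common library size) and are written as CPM, although the columns sum to between 894269 and 1058777. The same tables hold the authors' log2 fold changes and mean log2 CPM, their likelihood ratio as a score, and their p-values with the adjusted value (FDR). The submitters' processing notes name Bowtie 1.2.3, TopHat2 2.1.1, HTSeq 0.11.2, edgeR 3.26.8 and the genome build mm9, with no role for each. No mm9 genome was used here, so no coordinates are given. Gene symbols are those of the deposited tables, and biotypes were taken by symbol from a RefSeq gene table of another build (GRCm38.p6), which matched 13392 of the 13838 genes.

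In each column every value was a whole multiple of the column's lowest nonzero value, within 0.01 read for 100% of the genes. Taking that value as 1 read, read numbers per library could be read back from the tables. They came to between 7947827 and 10682677 reads in the footprint libraries and between 8564582 and 12840349 in the total RNA libraries, and 1 read was worth between 0.0751 and 0.114 CPM. In RPF control 2 the lowest nonzero value lies so near to 0.1 that an automatic check could not tell it from rounding. For that reason no count test uses this column. Count tests were run as alternatives on the 4 total RNA libraries, and on footprints only without RPF control 2. DESeq2, limma-voom and the likelihood ratio test, planned for footprints and for translational efficiency over all libraries, were not run there.

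The plan made before the data were examined was edgeR's quasi-likelihood test on counts, with limma on log2(value + 1) if the values were not counts. The values were not counts, so limma 3.58.1 in R 4.3.3 gave the main results, with a variance prior that follows the mean and Benjamini-Hochberg adjustment at a threshold of 0.05. Genes were kept by edgeR's filterByExpr (edgeR 4.0.16, a minimum count of 10 and a minimum total of 15) on the reads read back from the tables. All fold changes are on the log2(CPM + 1) scale, which understates changes of genes with few reads. Knockdown was compared with control within footprints (12723 genes tested) and within total RNA (13436 genes), 2 libraries against 2 with 2 residual degrees of freedom. The change in translational efficiency (footprints over total RNA) was the interaction of assay and knockdown in 1 limma model over all 8 libraries (12358 genes). The tables were normalized separately, so this contrast is a difference between 2 differences, each taken within its own table. With 2 libraries per group, no exact test of a single gene can pass the threshold, and p-values come from models that share the spread between genes.

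Before the data were examined, 32 gene lists were fixed, from translation factors and histones to pluripotency, lineage, stress and metabolic genes and fibroblast markers as another cell type. Each list with at least 3 tested members was tested with camera at a preset correlation of 0.01, on the log2 matrix and not on a count object as planned. Calls were repeated with an estimated correlation and with fry. With an estimated correlation camera works on the residual degrees of freedom of the fit, 2 per assay and 4 over all 8 libraries. It could hardly pass a list after adjustment in that setting. Members past the threshold were counted over all genes and adjusted over the list alone. The genes named were set by a rule fixed in advance. It takes 10 genes always (Eif4a2, Eif4a1, Eif4a3, H3f3a, H3f3b, Ddx6, Usp9x, Pou5f1, Nanog and Sox2). It takes the 8 largest changes per direction among genes that passed, or, where fewer passed, up to 5 with the smallest p per direction as values that did not pass, with at least 1 CPM in every group, no overlap between groups, a usual symbol and no small RNA or pseudogene. It also takes up to 4 members with the smallest adjusted p of each list called by the set test. Any other gene is named as chosen after its values were seen. The values of 3 list members that the rule takes are not reported here.

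Alternatives were DESeq2 size factors and upper-quartile factors for scaling, TMM over all 8 libraries for efficiency, no low-count filter or a filter of 50 reads, a pseudocount of 0.1, genes over 1% of a library left out, a threshold of 0.1, a minimum fold of 1.2, each library left out in turn, the replicate number as a block, and all 8 libraries in 1 fit with 4 residual degrees of freedom. DESeq2 1.42.0, limma-voom, the likelihood ratio test and the quasi-likelihood test were run on total RNA. TMM within each assay, planned as an alternative for efficiency, is what the deposited values already hold, so the scaling over all 8 stood as the alternative to it.

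The tests were tried on simulated reads for the real genes, with a seeded set of genes changed 2-fold or 4-fold. limma recovered 34% of the 2-fold and 83% of the 4-fold changes in footprints (12723 genes), 43% and 91% in total RNA (13436 genes), and 13% and 68% in efficiency (12358 genes), with 19, 5 and 6 false calls. Each gene was simulated with the same dispersion in both groups. The real total RNA pairs were uneven, with an SD of log2 differences of 0.135 for the knockdown and 0.45 for the control. The recovered shares may therefore not hold for the real libraries. The 8-library fit (12358 genes) made 29 false calls in footprints and 5 in total RNA, and the likelihood ratio test made 37 and the quasi-likelihood test 6 in total RNA (13436 genes). The set test called the list raised 1.5-fold and 0 of 30 unchanged lists in each of the 3 comparisons. Genes were simulated independently and these lists were drawn at random. The simulation therefore cannot show how often the preset correlation gives false calls for lists whose members vary together. Real lists of that kind were ribosomal proteins in total RNA (estimated correlation 0.654) and mitochondrially encoded genes in footprints (0.89).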

Results

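Footprints and total RNA were measured in mouse J1 embryonic stem cells after shRNA knockdown of eIF4A2, a DEAD-box RNA helicase of the translation initiation machinery, and in cells with control shRNAs. Each of the 4 groups held 2 libraries. Footprint depth was 7947827 and 9573832 reads in the knockdown and 9458103 and 10682677 in the control. Total RNA depth was 12228408 and 12840349 reads in the knockdown and 8564582 and 9489221 in the control. The series title names developmental potency and histone H3.3 transcripts as the subject, and the comparisons ask which genes differed in footprints, in total RNA and in the ratio between them.

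Eif4a2 itself was lower in every knockdown library than in every control library. Its total RNA was 600 ± 24.6 CPM in the knockdown and 854 ± 163 CPM in the control (SD, n = 2 libraries each), 70.3% of control. Its footprints were 232 ± 111 CPM against 402 ± 9.91 CPM, 57.8% of control, and the knockdown libraries differed, at 77.3% of the control mean in replicate 1 and 38.2% in replicate 2. Between 1467 and 4126 footprint reads per library stood behind these values. Eif4a2 did not pass limma's threshold in footprints (log2 fold change -0.88 ± 0.29 SE, adjusted p = 0.273) or in total RNA (-0.50 ± 0.18, adjusted p = 0.29). The paralog Eif4a1, the major eIF4A of the cap-binding complex, had values of -0.38 ± 0.27 in footprints and -0.29 ± 0.20 in total RNA, and the exon junction helicase Eif4a3 had -0.07 ± 0.18 and 0.05 ± 0.16, with a sign that changed in each assay when 1 library was left out (0.10 in footprints without knockdown 1, -0.11 in total RNA without control 1). The 3 eIF4A genes as a list were not called in either assay.

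In footprints, genes of the 2-cell-like state, a rare state of stem cell cultures that expresses genes of the 2-cell embryo, rose as a group in the knockdown. Of 19 measured members 17 had positive log2 fold changes, with a median of 0.71 (1.64-fold), and camera called the list (adjusted p = 1.52e-06, but adjusted p = 0.629 with an estimated correlation). Adjusted over the list alone 7 members passed, and 0 passed over all genes tested. Zscan4f, a zinc finger protein of the 2-cell embryo, had 15.8 ± 3.94 CPM in the knockdown and 2.48 ± 0.556 CPM in the control (SD, n = 2), a log2 fold change of 2.27 ± 0.29 with an adjusted p of 0.0692. Usp17le, a deubiquitinase gene, had 13.6 ± 3.82 against 2.72 ± 0.206 CPM (1.95 ± 0.29, adjusted p = 0.0703). Zscan4d (1.31 ± 0.36) and Gm12794 (1.49 ± 0.42) were also above control in both libraries. Zscan4 and Usp17l genes have near-identical copies, so the split of reads among them is uncertain.

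**Figure D1:**
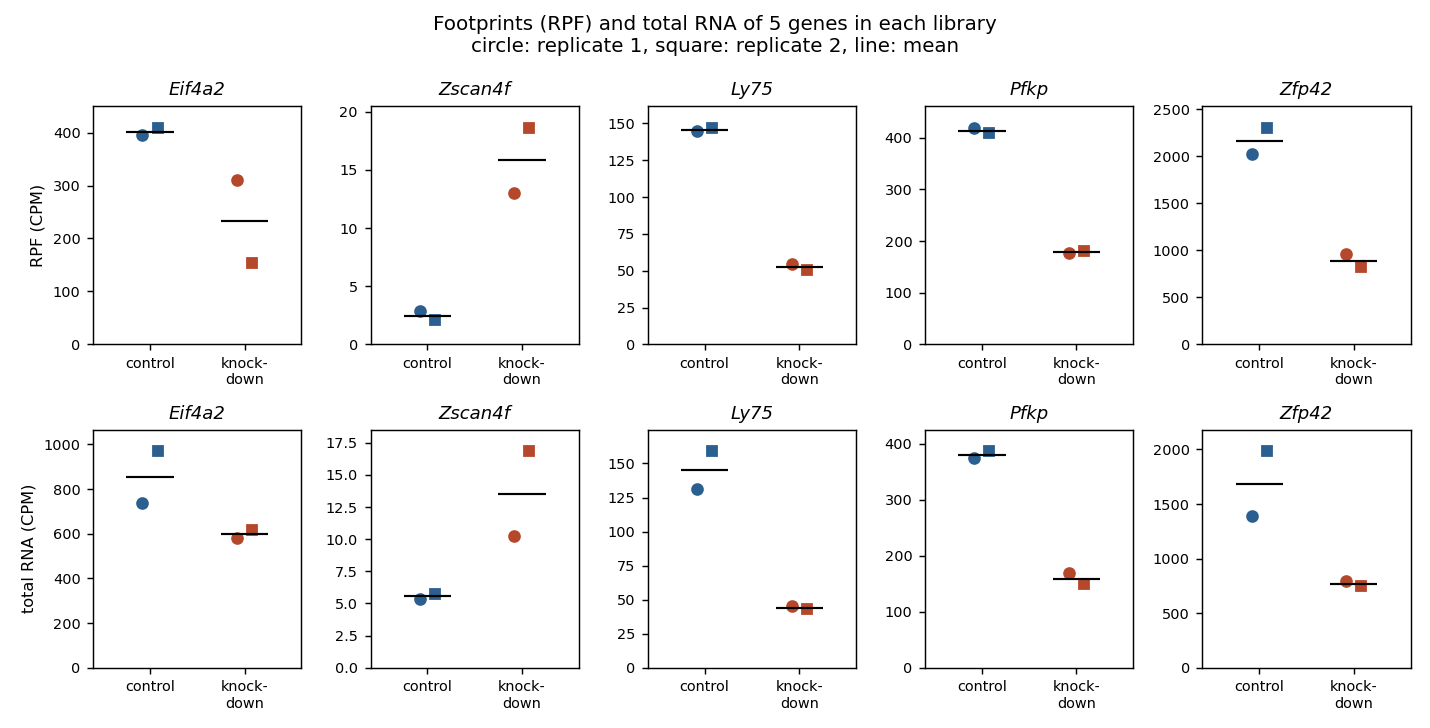
Footprint values (upper row) and total RNA values (lower row) in CPM of 5 genes in the 2 control and 2 eIF4A2 knockdown libraries, with circles for replicate 1, squares for replicate 2 and a line at the mean. Zscan4f lies higher in every knockdown library than in every control library, while Eif4a2, Ly75, Pfkp and Zfp42 lie lower, as for Ly75 in footprints (mean 52.6 against 145.7 CPM).

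Core pluripotency factors were called lower as a group in footprints, with 18 of 25 members negative and a median of -0.29 (camera adjusted p = 0.00212, adjusted p = 0.629 with an estimated correlation). Adjusted over the list alone 8 members passed as lower. Zfp42 (Rex1), a marker of naive stem cells, had 890 ± 98.5 CPM in the knockdown and 2164 ± 194 CPM in the control (log2 fold change -1.28 ± 0.20, adjusted p = 0.0703). The transcription factors Tbx3 (-0.95 ± 0.17), Nr0b1 (-0.79 ± 0.16) and Klf2 (-0.64 ± 0.16) were lower in both libraries without passing over all genes. Nanog had -0.66 ± 0.21, Sox2 -0.61 ± 0.20 and Pou5f1 -0.12 ± 0.19, and none passed over all genes tested. The calls for the pluripotency and 2-cell-like lists held with each of the 4 footprint libraries left out.

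Glycolysis genes were also called lower as a group in footprints (14 of 18 negative, median -0.37, camera adjusted p = 9.81e-05, but adjusted p = 0.629 with an estimated correlation), and 8 members passed adjusted over the list alone. Pfkp, a phosphofructokinase, had 179 ± 3.51 CPM against 414 ± 7.21 CPM (-1.20 ± 0.15, adjusted p = 0.0692). Pgk1 (-0.66 ± 0.18), Tpi1 (-0.67 ± 0.19) and Ldha (-0.70 ± 0.20) did not pass over all genes. Replication-dependent histones, whose mRNAs lack poly(A) tails, were called lower (38 of 47 negative, median -0.33, camera adjusted p = 3.86e-06, but 0.629 with an estimated correlation), led by Hist1h4d (-0.89 ± 0.22), Hist1h3b (-1.12 ± 0.29), Hist1h2aa (-0.90 ± 0.25) and Hist1h3a (-0.83 ± 0.25). Nuclear genes of oxidative phosphorylation were called lower (57 of 82 negative, median -0.16, camera adjusted p = 0.000519, but 0.629 with an estimated correlation), with Ndufb2 (-0.80 ± 0.17), Ndufa4l2 (-1.82 ± 0.39), Atp5j2 (-0.70 ± 0.20) and Sdhb (-0.59 ± 0.18) ahead. Ndufa4l2 entered this list by a name pattern and had few reads, at 0.675 and 0.837 CPM in the knockdown libraries. The glycolysis call was also lost without RPF control 1 (adjusted p = 0.0794), the histone call without RPF knockdown 1 (0.0743) or RPF control 2 (0.24), and the oxidative phosphorylation call without RPF knockdown 1 (0.175).

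Of the smaller lists in footprints, 4 were called by camera at the preset correlation (adjusted p = 0.0108 for germline, 0.0274 for interferon, 0.0402 for endoderm and 0.0276 for mitochondrially encoded genes) but not with an estimated correlation (adjusted p = 0.629 for each). Germline genes had a median of 0.44 (9 of 10 positive), with Taf7l (1.26 ± 0.30), Tdrd1 (1.43 ± 0.41) and Sycp1 (0.99 ± 0.42) above control and Hormad1 (-1.20 ± 0.31) below it. Interferon response genes had a median of -0.48 (5 of 7 negative), with Ddx58 at -0.86 ± 0.23, Stat2 at -0.49 ± 0.19 and Oas1a at -0.71 ± 0.28. Endoderm genes had a median of -0.34 (8 of 11 negative), among them the basement membrane genes Lama1 (-1.20 ± 0.19), Col4a2 (-0.55 ± 0.24) and Lamb1 (-0.34 ± 0.16) and the chemokine receptor Cxcr4 (-0.93 ± 0.40). The 7 mitochondrially encoded genes were all negative (median -0.73), with mt-Nd6 at -1.16 ± 0.48, mt-Cytb at -0.73 ± 0.49, mt-Nd5 at -0.80 ± 0.55 and mt-Nd2 at -0.88 ± 0.61. RPF control 2 held 0.178% of its reads in mitochondrial mRNAs, against 0.0517% to 0.0652% in the other 3 footprint libraries. Without it the mitochondrial median was 0.216, the opposite direction (adjusted p = 0.255), and without RPF knockdown 1 the call was lost too (0.295). The germline call was lost without RPF knockdown 2 (0.122) or RPF control 1 (0.0501), the interferon call without RPF knockdown 2 (0.0866) or RPF control 2 (0.0764), and the endoderm call without RPF knockdown 2 (0.172) or RPF control 1 (0.203).

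Other footprints with the smallest p were higher for Cilp2 (12.4 ± 0.177 against 2.71 ± 0.375 CPM), Casq2, a calcium-binding protein of muscle (23.1 ± 0.112 against 7.40 ± 0.652), Sfn, a 14-3-3 protein (179 ± 39.7 against 71.1 ± 6.67) and Myl9, a myosin light chain (9.36 ± 2.89 against 1.33 ± 0.0653). Mean total RNA was also higher for Cilp2, Sfn and Myl9, but not for Casq2, which had few reads there (0.885 against 1.35 CPM). They were lower for the endocytic receptor Ly75 (52.6 ± 2.78 against 145.7 ± 1.64 CPM), the septin Sept1 (66.6 ± 1.56 against 182.8 ± 25.6), Hmces (43.0 ± 5.20 against 118.0 ± 7.85) and the secreted phosphoprotein Spp1 (242.8 ± 28.7 against 703.7 ± 112). Over all 12723 genes limma called 0 in footprints, with a smallest adjusted p of 0.0692, although 1636 genes had an unadjusted p below 0.05 where chance gives 636. The groups did not overlap in 44.8% of genes, where chance gives 33.3%. Both chance figures are averages. Genes of a library vary together, so neither excess by itself shows an effect of the knockdown. Log2 values of genes with at least 10 CPM differed with an SD of 0.423 between the knockdown libraries and 0.372 between the control libraries. Across groups the SD was 0.43 and 0.422 against control 1 and 0.521 and 0.438 against control 2 (knockdown 1 and 2). The knockdown pair was thus about as far apart as either was from control 1. With all 8 libraries in 1 fit 43 genes were called higher and 46 lower, the named genes of this paragraph among them, but 0 were called when RPF control 2 was left out of that fit and 205 when total RNA control 2 was. Leaving out 1 footprint library from the main fit gave 20 calls without knockdown 1, 36 without knockdown 2, 4 without control 1 and 1 without control 2. edgeR's likelihood ratio test without RPF control 2 called 44. The authors' deposited table listed 101 genes as higher and 114 as lower at an FDR below 0.05, with FDRs of 6.27e-07 for Zscan4f and 1.19e-06 for Ly75.

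**Figure D2:**
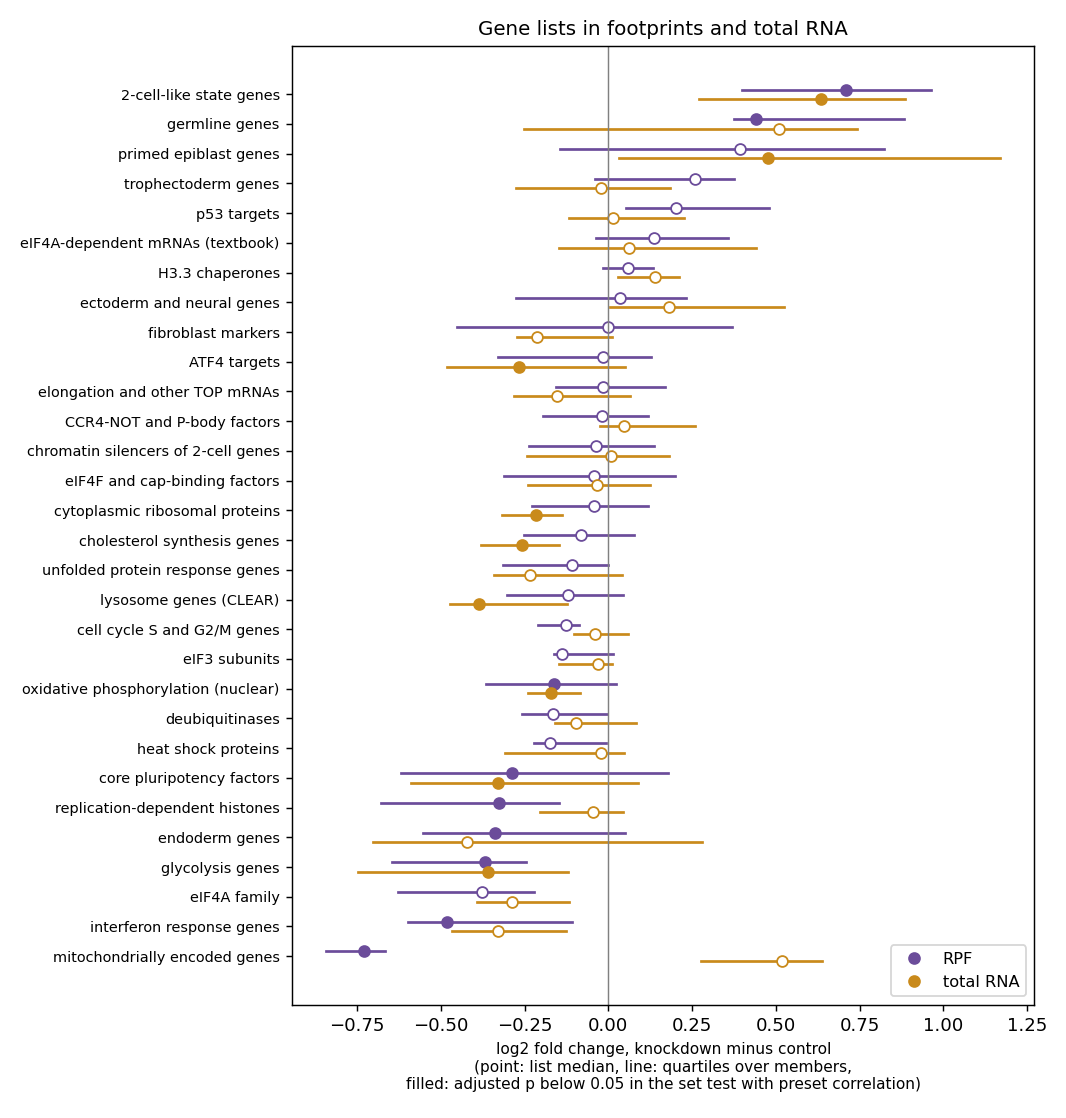
Median log2 fold change (points) and quartiles over members (lines) of the lists tested in both assays, footprints in purple and total RNA in orange, with filled points for lists called by camera at a preset correlation. The 2-cell-like list lies highest in both (0.71 and 0.64), and the mitochondrially encoded list parts, at -0.73 in footprints and 0.52 in total RNA.

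In total RNA, 2-cell-like genes and primed epiblast genes rose as groups in the knockdown by camera at the preset correlation. With an estimated correlation the adjusted p was 0.742 for the 2-cell-like list and 0.665 for the primed epiblast list. Of 21 measured 2-cell-like genes 18 were positive (median 0.64, camera adjusted p = 7.55e-06), and 7 passed adjusted over the list alone. Zscan4d had 21.1 ± 8.69 CPM against 6.91 ± 1.21 CPM (log2 fold change 1.44 ± 0.30, adjusted p = 0.128), with Zscan4c (1.17 ± 0.26) and Zscan4f (1.11 ± 0.26) alongside. Of 10 primed epiblast genes, which mark the stage after the naive state, 8 were positive (median 0.48, adjusted p = 0.00197), 5 of them past the threshold adjusted over the list alone and 1 lower. The growth factor Fgf5 had 3.73 ± 0.075 CPM against 0.454 ± 0.328 CPM (1.72 ± 0.24). The DNA methyltransferases Dnmt3a (489 ± 10.9 against 221.9 ± 36.2 CPM, 1.15 ± 0.16) and Dnmt3b (0.89 ± 0.13) and the transcription factor Otx2 (1.18 ± 0.17) were higher in both libraries. Core pluripotency factors fell as a group (18 of 25 negative, median -0.33, adjusted p = 0.00579, adjusted p = 0.665 with an estimated correlation), with Nr0b1 at -1.13 ± 0.20, Zfp42 at -1.11 ± 0.21, Tet2 at -0.73 ± 0.18 and Fgf4 at -0.59 ± 0.15. Pou5f1 (-0.27 ± 0.15), Nanog (-0.42 ± 0.13) and Sox2 (-0.54 ± 0.20) did not pass. The 3 calls held with each total RNA library left out.

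Metabolic lists were called lower in total RNA by camera at the preset correlation, but none of them with an estimated correlation. Glycolysis genes were negative in 16 of 18 cases (median -0.36, camera adjusted p = 0.000126, 0.665 with an estimated correlation), with 7 lower and 1 higher adjusted over the list alone. Pfkp had 159 ± 14.4 against 380.2 ± 8.90 CPM (-1.25 ± 0.14, adjusted p = 0.0819), followed by Pgk1 (-0.95 ± 0.16), Aldoc (-1.12 ± 0.20) and Aldoa (-0.80 ± 0.14). Lysosome genes were negative in 18 of 20 (median -0.38, adjusted p = 0.000345, 0.665 with an estimated correlation), with Ctsb (-0.61 ± 0.15), Gaa (-0.43 ± 0.13), Ctsa (-0.52 ± 0.16) and Npc2 (-0.55 ± 0.18) ahead. Cholesterol synthesis genes were negative in 17 of 19 (median -0.26, adjusted p = 0.00197, 0.758 with an estimated correlation), among them Msmo1 (-0.74 ± 0.16) and Insig1 (-0.39 ± 0.13). These 3 calls held with each library left out. Of 85 cytoplasmic ribosomal protein genes 83 were negative (median -0.21, adjusted p = 7.55e-06, 0.86 with an estimated correlation), with Rpl22l1 (-0.69 ± 0.16), Rps6 (-0.50 ± 0.19), Rpl10l (-0.54 ± 0.21) and Rpl39 (-0.37 ± 0.16) ahead. Nuclear oxidative phosphorylation genes were negative in 68 of 82 (median -0.17, adjusted p = 0.00197, 0.86 with an estimated correlation), led by Ndufv3 (-0.69 ± 0.16), Ndufa4l2 (-1.25 ± 0.34), Cox5a (-0.39 ± 0.13) and Ndufb3 (-0.58 ± 0.20). Ndufa4l2 had few reads here too, at 0.158 and 0.977 CPM in the knockdown libraries. ATF4 targets, which respond to amino acid shortage, were negative in 12 of 19 (median -0.27, adjusted p = 0.0332, 0.665 with an estimated correlation), with Asns (-1.12 ± 0.20), Aldh1l2 (-1.12 ± 0.20), Atf5 (-0.61 ± 0.15) and Psat1 (-0.56 ± 0.15). Without total RNA control 2 the ribosomal protein call was lost (adjusted p = 0.3) and the oxidative phosphorylation list had a median of 0.04, the opposite direction (0.452). The ATF4 call was lost without total RNA knockdown 2 (0.0602) or total RNA control 1 (0.0952).

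The single genes with the smallest p in total RNA were higher for Myl9 (8.13 ± 0.336 against 1.01 ± 0.021 CPM), Ccno (log2 fold change 2.19 ± 0.22), Prtg (35.2 ± 0.728 against 10.8 ± 1.18), the ephrin Efnb2 (32.9 ± 0.383 against 11.9 ± 0.788) and the cell death gene Pmaip1 (67.5 ± 5.99 against 26.6 ± 1.12). They were lower for Ly75 (44.2 ± 1.69 against 145.2 ± 19.4 CPM), Sept1 (31.6 ± 0.213 against 85.3 ± 4.75), the microtubule protein Mapt (8.96 ± 0.288 against 29.3 ± 0.0293), the dynein gene Dnah8 (35.9 ± 0.101 against 100.4 ± 15.0) and Emp1 (12.0 ± 1.94 against 38.1 ± 0.163). limma's adjusted p was 0.0819 for each, the smallest of all 13436 genes, so that 0 genes passed, while 2002 had an unadjusted p below 0.05 where chance gives 672. The groups did not overlap in 47.9% of genes, where chance gives 33.3%. As in footprints, neither excess by itself shows an effect of the knockdown, because genes of a library vary together. edgeR's quasi-likelihood test and limma-voom also called 0, DESeq2 called 272 and edgeR's likelihood ratio test 824. All 8 libraries in 1 fit gave 35 higher and 62 lower, and 0 when either RPF control 2 or total RNA control 2 was left out. The spread was uneven, since log2 values of genes with at least 10 CPM differed with an SD of 0.135 between the knockdown libraries and 0.45 between the control libraries. Control 1 differed less from knockdown 1 (0.323) and knockdown 2 (0.336) than from control 2. Control 2 differed from knockdown 1 by 0.445 and from knockdown 2 by 0.49. Without total RNA control 1 the main fit called 6191 genes, without control 2 it called 3411, without knockdown 1 it called 62 and without knockdown 2 it called 34. The authors' deposited table listed 297 genes as higher and 429 as lower at an FDR below 0.05.

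Fold changes in footprints and total RNA went together across genes. Over 12358 genes the log2 fold changes had a Pearson r of 0.655 and a Spearman rho of 0.614, and r was 0.692 over genes with at least 10 CPM, with the caution that genes are not independent replicates. Of the 93 genes higher in the authors' deposited table of footprints among the 12416 genes in both tables, 60 were also among the 267 higher in their table of total RNA, where independent lists would share 2. Of the 112 lower in footprints, 81 were among the 405 lower in total RNA, where independent lists would share 3.65, and 1 gene, Wdr95, named after its values were seen, was called in opposite directions (log2 fold changes of 1.75 in footprints and -2.86 in total RNA in the authors' deposited table). The labels do not say whether footprints and total RNA came from the same cultures, so part of this overlap may come from shared cultures.

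No single gene passed the threshold for a change in translational efficiency with all 8 libraries. limma's interaction called 0 of 12358 genes, with a smallest adjusted p of 1, and 192 had an unadjusted p below 0.05 where chance gives 618. Among the genes with the smallest p, efficiency values were positive for the kinase Mapk15 (2.31 ± 0.65), Sertad4 (1.32 ± 0.39), Reep1 (1.36 ± 0.43), the ribosomal protein Rpsa (0.87 ± 0.28) and the potassium channel Kcnh3 (1.46 ± 0.47). They were negative for the mitochondrial carrier Slc25a34 (-1.11 ± 0.22), the endoderm gene Dab2 (-1.01 ± 0.30), Ube2k (-0.67 ± 0.21), Polr2f (-0.60 ± 0.20) and the nucleoside kinase Nme1 (-0.90 ± 0.30). Footprint means hardly differed between knockdown and control for Kcnh3 (2.26 against 2.31 CPM) and Dab2 (6.12 against 6.26). Their total RNA means did differ (2.06 against 7.60 and 6.66 against 2.87 CPM). Mapk15 had few total RNA reads (1.16 against 1.85 CPM) and Reep1 few footprints (1.98 against 1.02 CPM). With 1 library left out 1 gene was called without RPF knockdown 2 (Neat1, 3.94 ± 0.32, adjusted p = 0.026) and 1 without RPF control 1 (Mir291a, -3.57 ± 0.28, adjusted p = 0.0113), both non-coding RNAs named after their values were seen. The SE of an efficiency change had a median of 0.313 against 0.235 in footprints and 0.191 in total RNA.

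The histone H3.3 genes had values below control in both assays without passing. H3f3a had 188.8 ± 13.8 against 256.1 ± 47.6 CPM in footprints (log2 fold change -0.43 ± 0.18, adjusted p = 0.372) and -0.29 ± 0.26 in total RNA, an efficiency change of -0.14 ± 0.34. H3f3b had 544.5 ± 3.88 against 648.0 ± 12.9 CPM in footprints (-0.25 ± 0.17, adjusted p = 0.567) and -0.34 ± 0.19 in total RNA, an efficiency change of 0.09 ± 0.25. Without total RNA control 2 the total RNA value of H3f3a was 0.10, the opposite direction. Ddx6, a helicase of P-bodies, had -0.36 ± 0.18 in footprints, -0.02 ± 0.15 in total RNA and -0.33 ± 0.24 in efficiency, and the deubiquitinase Usp9x had -0.17 ± 0.20, -0.16 ± 0.17 and -0.01 ± 0.27. Efficiency changes were, for Eif4a2, -0.38 ± 0.40, for Eif4a1, -0.09 ± 0.34, for Eif4a3, -0.12 ± 0.26, for Pou5f1, 0.15 ± 0.25, for Nanog, -0.24 ± 0.27 and, for Sox2, -0.07 ± 0.30.

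As groups, 3 lists were called in efficiency by camera at the preset correlation, and none with an estimated correlation (adjusted p = 0.818 for each). Ribosomal proteins were higher (63 of 85 positive, median 0.17, adjusted p = 2.01e-05), led by Rpsa, Rps2 (0.80 ± 0.28), Rplp2 (0.51 ± 0.23) and Rps10 (0.51 ± 0.26). Replication-dependent histones were lower (38 of 47 negative, median -0.26, adjusted p = 0.000143), led by Hist1h4d (-0.83 ± 0.29), Hist1h3b (-1.29 ± 0.45), Hist1h2bp (-0.93 ± 0.44) and Hist1h3a (-0.78 ± 0.40). Mitochondrially encoded genes were lower (7 of 7 negative, median -1.11, adjusted p = 0.000143), led by mt-Cytb (-1.47 ± 0.81), mt-Nd2 (-1.67 ± 0.97), mt-Nd5 (-1.32 ± 0.85) and mt-Co1 (-0.82 ± 0.59). The ribosomal protein call was lost without RPF knockdown 2 (adjusted p = 0.106), RPF control 1 (0.151) or total RNA control 2 (0.984). The histone call was lost without RPF knockdown 1 (0.367), RPF control 2 (0.907), total RNA knockdown 1 (0.0894) or total RNA control 1 (0.252), and the mitochondrial call without RPF control 2 (0.836) or total RNA control 2 (0.265).

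**Figure D3:**
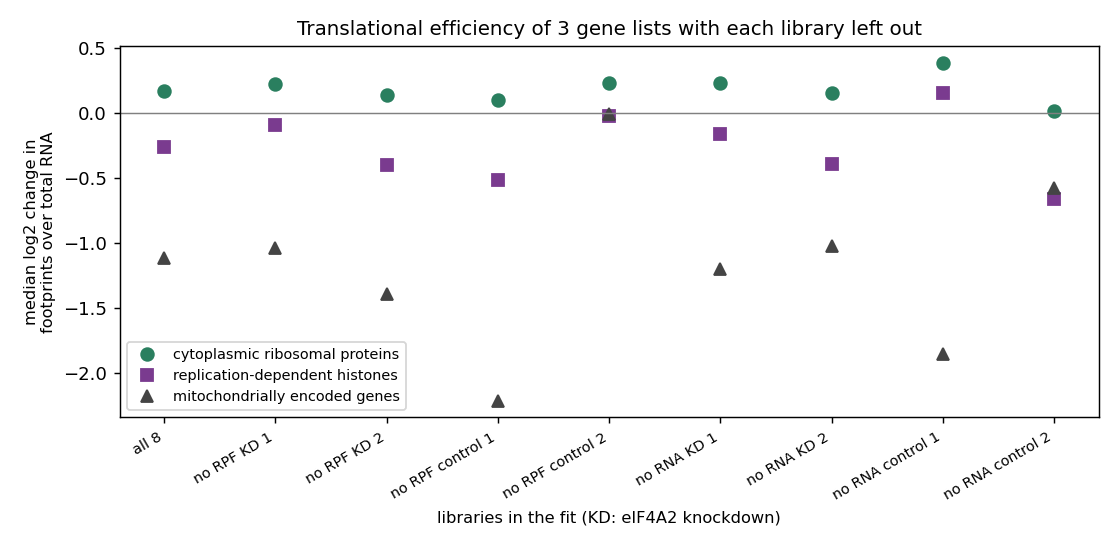
Median log2 change of footprints over total RNA of 3 gene lists (ribosomal proteins as circles, replication-dependent histones as squares, mitochondrially encoded genes as triangles) with all 8 libraries and with each library left out. Mitochondrially encoded genes lie at -1.11 with all libraries and at -0.01 without RPF control 2.

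The remaining lists were not called. In footprints and total RNA the medians were -0.38 and -0.29 for the eIF4A family, -0.04 and -0.03 for cap-binding factors, -0.14 and -0.03 for eIF3 subunits, -0.02 and 0.05 for CCR4-NOT and P-body factors, and -0.02 and -0.15 for elongation and other TOP mRNAs. They were 0.14 and 0.06 for textbook eIF4A-dependent mRNAs, 0.06 and 0.14 for H3.3 chaperones, -0.17 and -0.10 for deubiquitinases, 0.04 and 0.18 for ectoderm and neural genes, and 0.26 and -0.02 for trophectoderm genes. They were -0.11 and -0.23 for the unfolded protein response, -0.17 and -0.02 for heat shock proteins, -0.13 and -0.04 for cell cycle genes, -0.04 and 0.01 for silencers of 2-cell genes, and 0.20 and 0.01 for p53 targets. Fibroblast markers, the other cell type considered, had medians of 0.00 and -0.21. The H3.3 list had 2 members, too few to test, with medians of -0.34 and -0.32, and the mesoderm list had a footprint median of 0.49 over 6 members and only 2 members in total RNA (median 0.02). Lists called in 1 assay alone had medians in the other of 0.39 for primed epiblast genes, -0.02 for ATF4 targets, -0.12 for lysosome genes, -0.08 for cholesterol synthesis genes and -0.04 for ribosomal proteins in footprints. In total RNA these were 0.51 for germline genes, -0.33 for interferon genes, -0.42 for endoderm genes, -0.05 for histones and 0.52 for mitochondrially encoded genes. A call in 1 assay alone does not show a difference between the assays.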

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

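The set tests of this part and the fits with a library left out were planned. The comparisons of list medians without a single control library were chosen after the results were seen. Changes in footprints and in total RNA differed, by the interaction test on lists at a preset correlation, for cytoplasmic ribosomal proteins (median efficiency change 0.174), replication-dependent histones (-0.264) and mitochondrially encoded genes (-1.11). None of the 3 passed with an estimated correlation (adjusted p = 0.818 each) or with fry (0.899 each). Each of the 3 medians moved to near 0 or past it when a single control library was left out. Without RPF control 2, which held the highest shares of mitochondrial mRNA (0.178%) and mitochondrial rRNA (4.31% against 0.894% to 2.59%) among footprint libraries, the mitochondrial median was -0.00729. Without total RNA control 2 the ribosomal protein median was 0.0136, and without total RNA control 1 the histone median was 0.153 (-0.0197 without RPF control 2). The calls for ribosomal proteins and histones were also lost without single knockdown libraries. These 3 efficiency changes may therefore come from differences between single libraries, control libraries among them. An effect of eIF4A2 on the efficiency of these mRNAs stays open.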

How the results depend on the processing

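The no-trend fit, the crossed block, the fits less a control 2 library, the quasi-likelihood test and the pseudocount of 0.1 for total RNA and efficiency were chosen after the data were seen. DESeq2, limma-voom and the likelihood ratio test were not run for footprints and efficiency over all libraries, because no count test uses RPF control 2. No count of genes moved from 0 with DESeq2 size factors, upper-quartile factors, no low-count filter, a filter of 50 reads, a pseudocount of 0.1, no variance trend, a minimum fold of 1.2, or genes over 1% of a library left out.

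In footprints 45 genes were called at a threshold of 0.1, 89 with all 8 libraries in 1 fit (0 less RPF control 2, 205 less total RNA control 2) and 44 by the likelihood ratio test less RPF control 2. In total RNA 58 were called at a threshold of 0.1, 272 by DESeq2, 824 by the likelihood ratio test (3256 less total RNA control 2) and 97 with all 8 libraries in 1 fit (0 less either control 2 library). Of the calls of the 8-library fit 84 of 89 and 97 of 97 were also in the authors' deposited table. Leaving out each library gave between 1 and 36 genes in footprints, 34 and 6191 in total RNA, and 0 and 1 in efficiency, where the lone library was assumed to vary like the others. The total RNA counts without a control library (6191 and 3411) took their spread from the knockdown pair, which differed by an SD of 0.135. No other alternative called a gene in efficiency.

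The replicate numbers share only a number, and same-numbered deviations correlated at 0.132 between the footprint groups and -0.173 between the total RNA groups. Between footprints and total RNA they correlated at 0.105 for the knockdown groups, 0.199 for the control groups, 0.13 for footprint knockdown with total RNA control and 0.0102 for footprint control with total RNA knockdown. The replicate block gave 21 genes in footprints, 636 in total RNA and 0 in efficiency, and 10, 13 and 3 lists. With the numbers crossed the block gave 39 genes in footprints and 924 in total RNA.

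Camera called 9 lists in footprints, 9 in total RNA and 3 in efficiency at the preset correlation. Fry called 0, 0 and 0, the cause of which was not tested. With an estimated correlation camera also called 0, 0 and 0. Core pluripotency factors in footprints had an estimated correlation of only -0.0168, yet camera's p rose from 0.000342 (preset) to 0.0575. With 2 residual degrees of freedom per assay camera could hardly pass a list in this way. For lists with an estimate near 0 the lost calls therefore say little for or against the list. Other lists had estimates far above the preset 0.01. In footprints these included glycolysis genes (0.569) and histones (0.549), and in total RNA ribosomal proteins (0.654) and oxidative phosphorylation (0.558). For such lists camera at the preset correlation may have overstated the evidence. With each library left out it called between 6 and 14 in footprints, 10 and 13 in total RNA, and 1 and 8 in efficiency. Adjusted p over the libraries left out ran from 1.06e-15 to 0.295 for mitochondrially encoded genes in footprints (reversed without RPF control 2, 0.255). It ran from 7.66e-12 to 0.452 for oxidative phosphorylation in total RNA (reversed without control 2). For histones in efficiency it ran from 7.81e-19 to 0.907 (reversed without total RNA control 1, 0.252). For ribosomal proteins in efficiency it ran from 3.51e-14 to 0.984. The 0.984 came without total RNA control 2, where camera's direction was reversed but the list median stayed positive (0.0136).

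Of 141 named gene and comparison pairs 18 changed sign under an alternative, 26 of 27 such values with 1 library left out, and the cause was not tested. The other was Usp9x efficiency, 0.031 with upper-quartile factors. With each library left out, footprint values ran from -0.23 to 0.10 for Eif4a3, -0.40 to 0.064 for Usp9x, -0.27 to 0.029 for Pou5f1, -1.68 to 0.22 for mt-Cytb, -1.71 to 0.10 for mt-Nd5 and -1.94 to 0.18 for mt-Nd2. Total RNA values ran from -0.11 to 0.22 for Eif4a3, -0.68 to 0.10 for H3f3a and -0.14 to 0.10 for Ddx6. Efficiency values ran from -0.89 to 0.13 for Eif4a2, -0.35 to 0.18 for Eif4a1, -0.29 to 0.045 for Eif4a3, -0.53 to 0.25 for H3f3a, -0.14 to 0.33 for H3f3b, -0.24 to 0.22 for Usp9x, -0.50 to 0.030 for Nanog, -0.33 to 0.19 for Sox2 and -1.68 to 0.037 for mt-Co1. Depth limits genes with few reads, since 3 reads stood for between 0.225 and 0.343 CPM.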

Other observations

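Values in the first 2 paragraphs describe genes chosen after their values were seen, as were Ak4 and Ddit4, and the tests on 2-cell-like genes and on single libraries were also chosen after the results were seen, while the test of HIF targets was fixed before its result was. Among genes lower in both assays in the authors' deposited table were Bnip3 (log2 fold changes of -1.46 in footprints and -1.27 in total RNA), Ndufa4l2 (-2.85 and -2.19) and P4ha1 (-0.85 and -0.87), known targets of hypoxia-inducible factor, as well as Bmp4 (-1.42 and -0.79). No enrichment was tested.

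Footprint libraries also held reads of small RNA genes, which are not translated. In the authors' deposited table of footprints 5 of 196 such genes were called higher and 10 lower. Among the lower ones were 3 of the 7 listed microRNA genes of the miR-290 cluster, which is active in embryonic stem cells. Mir291a had 55.6 and 48.3 CPM in the knockdown and 139.4 and 512.6 CPM in the control footprint libraries, Mir295 had 5.06 and 7.53 against 19.1 and 32.8 CPM, and Mir292 had 9.68 and 38.7 against 45.1 and 149.8 CPM. In total RNA the same genes had 14.5 and 13.9 against 10.7 and 12.2 CPM, 9.71 and 7.67 against 8.56 and 9.98 CPM, and 15.8 and 15.3 against 12.9 and 12.2 CPM.

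2-cell-like genes were called higher in both assays at the preset correlation, but not with an estimated correlation (adjusted p = 0.629 in footprints and 0.742 in total RNA). A shift of reads among the measured near-identical copies would leave their sum in place. The summed CPM of the multicopy members was at least 1.71 times higher in the lowest knockdown library than in the highest control library in either assay. Reads shifted to or from copies that were not measured would change this sum, so the sum cannot exclude such a shift. In footprints the sums were 69.0 and 103.3 CPM in the knockdown against 29.3 and 28.6 CPM in the control (12 members), and in total RNA 85.1 and 140.8 against 46.4 and 49.7 CPM (14 members). A single library does not account for it either, since the list median nearest to 0 with 1 library left out was 0.426. Variation between cultures in the share of 2-cell-like cells also stays open. The gap between groups in total RNA (1.71-fold) was about as wide as the largest ratio within a group (1.66-fold). In footprints the gap was wider (2.35-fold against 1.5-fold within a group), but with 2 cultures per group this cannot be told apart from an effect of the knockdown.

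Glycolysis genes were called lower in both assays at the preset correlation, but not with an estimated correlation (adjusted p = 0.629 in footprints and 0.665 in total RNA), and the footprint call was lost without RPF control 1 (0.0794). A candidate explanation was a lower output of hypoxia-inducible factor (HIF). A list of HIF targets outside glycolysis was drawn up, without Bnip3, Ndufa4l2 and P4ha1, whose values had been seen. Its 21 measured members had a median of -0.0559 in total RNA (notch 0.0902), nearer to 0 than to the glycolysis median of -0.36 as the test had required for excluding this explanation, and camera at the preset correlation gave p = 0.0764 in total RNA and p = 0.178 in footprints. That requirement was too weak. The list lacked the 3 targets seen before, which the authors' deposited table calls lower in both assays. The median in total RNA was also -0.192 without control 1, past the midpoint to the glycolysis median, -0.125 without control 2, -0.0945 without knockdown 1 and -0.0362 without knockdown 2, and in footprints it moved from -0.11 to -0.208 without control 2 and to -0.043 without knockdown 2. Of the 21 members 15 were negative in each assay, and Ak4 (-0.84 ± 0.13) passed in total RNA adjusted over the list alone, but had 0.10 in footprints. Ddit4, with the smallest p in footprints, went the other way (0.78 ± 0.19 in footprints and 0.59 in total RNA) without passing. A lower HIF output therefore stays open. A single library did not account for the pattern, since the glycolysis median nearest to 0 with 1 library left out was -0.292, and differences in culture density or medium between groups were not tested.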
